A study of Escherichia coli str. K-12 substr. MG1655 with 20 samples.

How the data were processed

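RNA sequencing measured transcript levels of Escherichia coli K-12 MG1655, the standard laboratory strain, in Gutnick medium, a minimal medium in which nitrogen was limited. The 20 libraries fall into 8 groups by the labels. They are an untreated nitrogen-rich group (Nplus, n = 3), an untreated nitrogen-starved group (Nminus, n = 3), starved cells given the solvent DMSO (n = 3), and starved cells given 1 of 5 peptides derived from sigma-54, the alternative sigma factor of nitrogen assimilation. The peptides carry the code names s54-WT (n = 3), Ss54-1, Ss54-2, Ss54-3 and Ss54-4 (n = 2 each). The series describes triplicates, but only 2 libraries of each of these 4 are listed. Every column name is the title of a sample except those of s54-WT, headed WT_1 to WT_3. These were taken as s54-WT because they match the end of its titles and all other columns belong to other groups, and nothing else in the sources ties them to this peptide. Treatment began at an OD600 of 0.5, and RNA was stabilised 80 min later. The treatment protocol gives a peptide dose of 10 µM and the sample characteristics give 10 mM, so the unit of the dose is unsettled, but the number was the same for all 5 peptides. A sampling time for the untreated groups is not given separately in the sources used here.

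Per the labels, the authors aligned reads with Bowtie2 and counted them per gene with featureCounts, per the submitters' processing notes, whose versions are not given in the sources used here. The deposited values are log2 CPM, read counts scaled to the library total, in 1 table with 4273 genes and a column for each library. Checked on the table, all libraries share nearly the same distribution of values, from -6.42 to 15.13, with medians that differed by at most 0.00141, which is what quantile normalization makes. Raw counts were not used here, so the depth of each library is unknown, and no counting interval or detection floor can be given. The common distribution gives every library the same highest values, so genes at the top ranks cannot rise further, and a general rise or fall of RNA per cell cannot be seen. At the top ranks values move in fixed steps, such as 0.433 from rank 1 to 2 and 0.263 from rank 2 to 3. A change there reflects a change of rank, so its size, SE and p-value measure a fold change only roughly. Ribosomal RNA and transfer RNA genes were absent from the table. The table gives gene symbols without coordinates or a genome build. Of the symbols, 4063 matched the current names of the reference list, 200 matched older names and 10 matched neither.

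Genes with a mean of at least 1 CPM over the 20 libraries were tested, which kept 4171 genes and left out 102. A linear model with a mean for each group was fitted to the log2 CPM values of all libraries in R 4.3.3 with limma 3.58.1, with an intensity trend in the empirical Bayes step. Each comparison used the two-sided moderated test of limma, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Errors of log2 fold changes are standard errors (SE) from this fit, and errors of levels are standard deviations (SD) between libraries. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples. The comparisons were starvation (Nminus against Nplus), the vehicle (DMSO against Nminus), each peptide against DMSO, and every pair of peptides. In all, 29 gene lists were tested for a shift against the remaining genes with camera of limma, with a preset correlation of 0.01 and adjustment over the 29 lists of a comparison. The same test with a correlation estimated from the data, and fry of limma, were run beside it. Intervals of a list's mean are 95% intervals from a limma fit to the mean level of the list in each library. This fit shares the spread of a list over all groups, so an interval may be too narrow for a group whose libraries vary more.

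Genes were named by a rule. It took, for each comparison of a treatment or of starvation, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, with at most 2 genes of the same three-letter prefix. It added up to 3 called members of each described list, 9 nitrogen and stress genes in every comparison (rpoN, glnA, glnG, glnK, amtB, nac, astC, pspA and relA), and 3 rises and 3 falls for each pair of peptides. The comparisons, the lists, the rule, the tests and most alternatives were fixed before the data were examined. Genes named outside the rule are marked as chosen after their values were seen. Families of at least 4 genes with a shared three-letter prefix were also tested with camera, a step added after the data were seen.

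The alternatives were no filter on low values, a mean CPM of at least 10, log2(CPM + 1), centring on library medians, a repeated quantile normalization, a fit on the 2 compared groups only, a replicate block, no intensity trend, library quality weights, each library left out in turn, the untreated starved libraries or their mean with DMSO as control, the other list tests, and the first gene of each operon only. Centring on the median log ratio to the mean library was added after the data were seen. Where a left-out library left a group with 1 library, that library was assumed to vary like the other groups. A replicate number may mark a shared day, so correlations of deviations from the group mean were checked. For DMSO and Nminus they lay between 0.116 and 0.289 over the 3 pairs of equal number, and a replicate block called 11 genes there against 10 without it. For s54-WT and DMSO they lay between 0.0603 and 0.189, and the block called 679 genes against 558. With the replicate block, the 4 other peptides against DMSO gave 3140, 3590, 3099 and 2778 genes, in the order of their numbers, and starvation gave 3622.

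On simulated data with 200 changed genes among 4171, in groups of the real sizes, the test recovered between 67.2% and 77.6% of changes of 0.5 log2 units. Changes of 1 log2 unit were recovered in 92.5% to 98.5% of cases. The share of false calls lay between 2.14% and 8.29%, with 3.85% to 8.29% over the 4 comparisons of 2 with 3 libraries. The simulation gave a gene the same spread in all groups and did not force a common distribution. In the real data, replicates differed by a median of up to 0.203 for Ss54-4 and 0.0997 for DMSO. These shares may therefore not hold for comparisons in which most genes were called.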

Results

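Transcript levels of 4273 genes were compared in 20 libraries of E. coli K-12 MG1655 that differed in nitrogen supply, solvent and peptide. The untreated nitrogen-rich, untreated starved, DMSO and s54-WT groups had 3 libraries each, and Ss54-1 to Ss54-4 had 2 each. All values were log2 CPM on a common distribution between -6.42 and 15.13, so the depth of a library is unknown. Replicates of a group correlated across genes with Pearson's r of 0.990 to 0.998, the lowest for Ss54-4, where genes are not independent replicates. The first principal component held 74.0% of the variance and the second held 17.2%. Group means of DMSO correlated across genes with those of the untreated starved cells at r = 0.998 and with s54-WT at r = 0.997. The means of Ss54-1 and Ss54-3 correlated at r = 0.991, and the means of Ss54-2 were closer to the nitrogen-rich cells (r = 0.938) than to DMSO (r = 0.748).

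Nitrogen starvation, the condition in which the peptides were tested, was measured by the untreated starved against the nitrogen-rich libraries. Genes that sigma-54 transcribes with the activator NtrC, which supply and recycle nitrogen, rose by far the most. The mRNA of glnK, a PII signalling protein, was 10.08 ± 0.14 log2 units higher (SE, n = 3 and 3, limma adjusted p = 2.5e-20), from a level of 3.50 ± 0.20 (SD) to 13.58. The ammonium channel gene amtB rose by 9.67 ± 0.07, to the highest level of the table, 15.13. Genes for pyrimidine catabolism (rutA 9.88, rutB 9.46), arginine catabolism (astC 9.77, astA 9.14), D-alanyl-D-alanine use (ddpX 8.96) and putrescine use (patA 8.63) rose alike. The largest falls were in flagellar genes (flgB -9.08 ± 0.27, flgC -8.15, fliI -8.03, fliF -7.83), the galactitol transporter gene gatB (-8.32), the methionine synthase gene metE (-7.99 ± 0.13), the aspartate transcarbamoylase gene pyrB (-7.53) and yidD (-7.50 ± 0.41).

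All 44 tested members of the NtrC sigma-54 list rose, with a median of 5.31 (camera of limma, adjusted p = 8.0e-16, and adjusted p = 0.040 with an estimated correlation). They included the glutamine synthetase gene glnA (2.94 ± 0.04), glnG, which encodes NtrC (2.35 ± 0.08), and nac, a regulator of nitrogen genes (8.31 ± 0.08). Of the other sigma-54 operons, all 15 members rose, with a median of 2.60 and the largest rises in the zinc-responsive zraP (6.20) and the propionate catabolism gene prpB (5.95). Camera gave adjusted p = 1.4e-05, but adjusted p = 0.18 with an estimated correlation. All 6 phage shock genes rose, among them pspA, the membrane stress effector, by 2.28 ± 0.12 (list adjusted p = 0.015 by camera, adjusted p = 0.25 with an estimated correlation). Of 29 formate hydrogenlyase and hydrogenase genes 20 rose and 2 fell, with fdhF, formate dehydrogenase, up by 3.26 (adjusted p = 0.021 by camera, adjusted p = 0.27 with an estimated correlation). The gene of sigma-54 itself, rpoN, rose by 0.30 ± 0.06 (limma adjusted p = 6.5e-05), and relA, the (p)ppGpp synthase, by 3.50 ± 0.09. Among the neighbours of rpoN, ptsN (-0.65) and npr (-1.50) fell, lptB rose (0.45), and the list as a whole was not called (median 0.09, mean -0.26, camera adjusted p = 0.82).

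The growth machinery went the other way. All 54 ribosomal protein genes fell, with a median of -3.48 and rpsJ at -6.79 (camera of limma, adjusted p = 8.0e-16, adjusted p = 0.19 with an estimated correlation). All 9 ATP synthase genes fell (median -2.61), as did 10 of 13 genes of the tricarboxylic acid cycle (median -2.54) and 44 of 48 flagellar and chemotaxis genes (median -4.56, 45 when adjusted over the list alone). Camera called these lists at adjusted p = 7.4e-05, 0.0017 and 1.3e-12, against 0.18, 0.19 and 0.18 with an estimated correlation. Of the biosynthetic lists, 5 were called lower. All 11 purine genes fell (median -4.74, purE -7.17), as did 10 of 11 arginine genes (median -3.52, carA -7.19), all 8 methionine genes (median -4.29, metK -5.19) and 7 of 8 pyrimidine genes (median -4.24, pyrE -5.06). These were called by camera at adjusted p between 1.3e-06 and 0.0013, each with adjusted p = 0.18 with an estimated correlation. All 13 genes of branched-chain amino acid synthesis fell (median -2.36, ilvC -7.00, camera adjusted p = 7.4e-05, adjusted p = 0.023 with an estimated correlation). All 23 iron acquisition genes fell too, with the enterobactin gene entC at -6.19 (median -3.17, camera adjusted p = 7.5e-09, adjusted p = 0.18 with an estimated correlation).

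Of the stress lists, those of sigma-S, SOS and PhoP and PmrA were called higher in starved cells. Of 25 genes of the general stress regulon of sigma-S 22 rose and 2 fell, with dps, the DNA-protecting ferritin, up by 5.53 and sodC up by 4.79 (median 3.25, camera adjusted p = 6.9e-07, adjusted p = 0.040 with an estimated correlation). Of 17 SOS genes 15 rose, sulA by 2.25 (adjusted p = 0.0013 by camera, 0.18 with an estimated correlation), and of 16 PhoP and PmrA genes 13 rose, arnB by 2.38 (adjusted p = 0.016 by camera, 0.18 with an estimated correlation). The lists for Nac-activated operons (5 rose, 9 fell), glutamate (1 rose, 3 fell), histidine (1 rose, 4 fell), tryptophan (4 rose), heat shock (6 rose, 8 fell), sigma-E (7 rose, 6 fell), Cpx (6 rose, 4 fell), Rcs and capsule (4 rose, 17 fell), oxidative stress (5 rose, 3 fell), efflux (7 rose, 2 fell) and anaerobic respiration (10 rose, 1 fell) were not called by camera, with adjusted p between 0.11 and 0.82. In all, limma called 3592 of 4171 genes (86.1%), 1932 higher and 1660 lower, of which 1033 and 999 passed a 2-fold change.

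**Figure D1:**
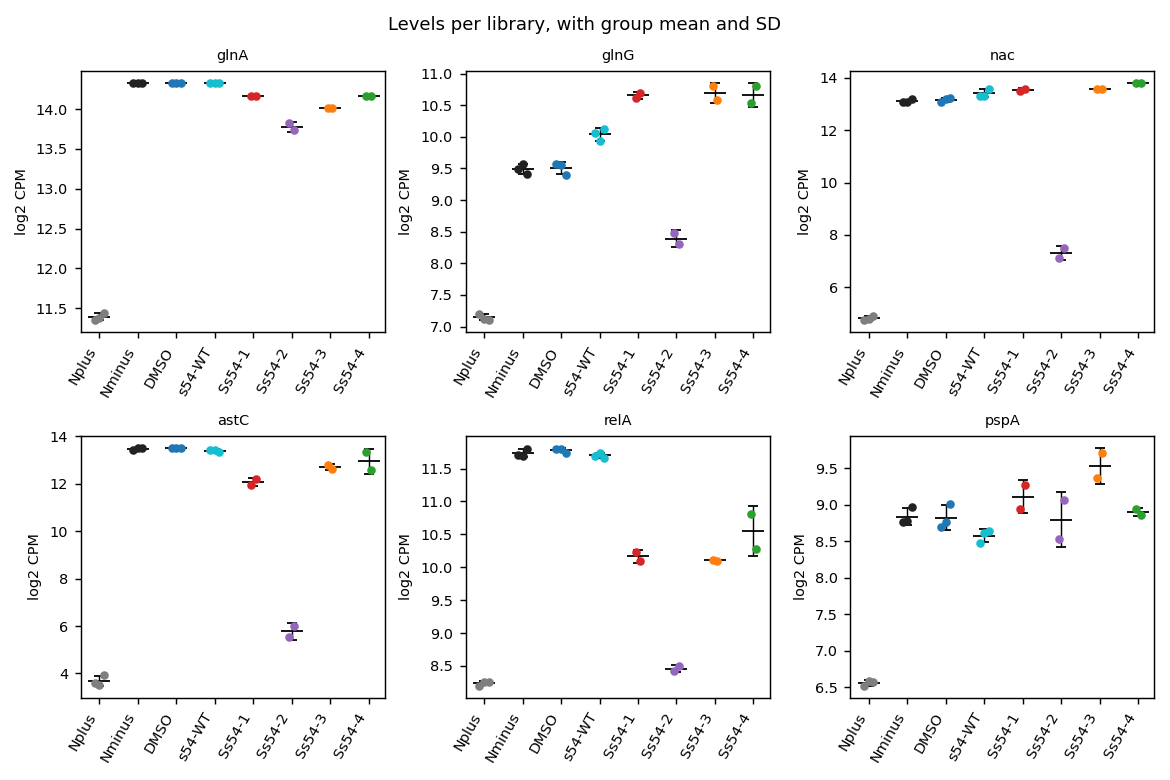
Levels of 6 genes in each library on the log2 CPM axis, by group, with the group mean (bar) and SD (whiskers). Transcripts of glnA, glnG, nac, astC and relA were high in starved, DMSO and s54-WT libraries and low in the nitrogen-rich ones, and the Ss54-2 libraries lay between these levels for all 5, while pspA did not follow the same order.

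The effect of the solvent was measured by DMSO against the untreated starved libraries. DMSO raised 2 genes of a trimethylamine N-oxide reductase, torC by 4.68 ± 0.12 log2 units (25.7-fold, SE, n = 3 and 3, limma adjusted p = 9.3e-15) and torA by 4.39 ± 0.15. It also raised hiuH, which encodes hydroxyisourate hydrolase, by 2.65 ± 0.15 (6.27-fold), the periplasmic methionine sulfoxide reductase genes yedY (1.42 ± 0.14) and yedZ (1.31 ± 0.17), and ylaC (0.88 ± 0.09). The response regulator gene torR fell by 1.40 (SE 0.11). These 7 genes followed from the naming rule, and the remaining 3 of the 10 called genes, torD (1.87 ± 0.11), yedV (0.56 ± 0.10) and yedW (0.43 ± 0.07), were chosen after their values were seen. No NtrC sigma-54 gene was called by limma, where 259 of 4171 genes had an unadjusted p under 0.05, and glnK, glnA and amtB differed by 0.00. The NtrC list was called by camera with a median of 0.08 and a mean of 0.09 (95% interval -0.02 to 0.19, adjusted p = 0.00028), but not with an estimated correlation (adjusted p = 0.98) or by fry (adjusted p = 0.92). No other list was called by camera, and the branched-chain, purine, SOS and anaerobic lists, near 0, differed in sign between median, mean or test. The 10 called genes were 0.240% of those tested. Library quality weights raised their number to 110, 51 higher and 59 lower, while a fit on the 2 groups gave 17.

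The first peptide, s54-WT, changed few genes by much. The largest rises were in the asparagine synthetase genes asnA, by 1.50 ± 0.19 log2 units (2.83-fold, SE, n = 3 and 3, limma adjusted p = 2.2e-04), and asnB, by 1.27 ± 0.23. An RNA chaperone gene of cold shock, cspA, rose by 1.11 ± 0.17. Smaller rises were seen for trpE, anthranilate synthase (0.86), and lhgO, hydroxyglutarate oxidase (0.85). Falls were seen for hiuH (-0.82 ± 0.15), yjbT (-0.76), stpA, an H-NS paralogue (-0.74), and ves (-0.73). The fall of hiuH held against DMSO alone, since hiuH was 1.83 higher under s54-WT than in untreated starved cells. Among nitrogen genes, glnG rose by 0.53 ± 0.08 and rpoN by 0.30 ± 0.06 (limma adjusted p = 9.3e-04 and 2.9e-03). The other fixed genes were not called, with glnK at -0.11 (adjusted p = 0.66), astC at -0.10, relA at -0.08, nac at 0.24 (adjusted p = 0.069) and pspA at -0.25 (adjusted p = 0.22). The levels of glnA and amtB, at the top of the common distribution, differed by 0.00.

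Of the 44 NtrC sigma-54 genes 21 rose under s54-WT and none fell (25 higher and 1 lower when adjusted over the list alone), with a mean of 0.29 (95% interval 0.19 to 0.40) and ddpB (0.76) and potI (0.70) among them. Camera gave adjusted p = 4.8e-11, but adjusted p = 0.31 with an estimated correlation. Of these 21, 20 were later genes of their operons and 1 was a first gene, and the first genes alone had a median of 0.00 (camera adjusted p = 0.61). In DMSO first genes lay at a median level of 13.33 and later genes at 9.48. The common distribution limits rises at the top, so the result for first genes says little. Of 16 Nac-activated genes 4 rose (camera adjusted p = 0.022, adjusted p = 0.70 with an estimated correlation). Of the neighbours of rpoN 3 of 5 rose, ptsN by 0.39 (adjusted p = 0.024, adjusted p = 0.62 with an estimated correlation). Also, 4 of 5 tryptophan genes rose (median 0.46, adjusted p = 0.001, adjusted p = 0.51 with an estimated correlation). Other sigma-54 operons (1 higher, 1 lower of 15), formate genes (2 lower of 29), phage shock genes (1 lower of 6, adjusted p = 0.064), ribosomal proteins (1 lower of 54), iron acquisition (1 higher of 23), and Rcs and capsule (1 lower of 22) were not called by camera. Neither were the remaining lists, in which cpxP (-0.60), a periplasmic stress gene, and rpoH (-0.56), heat shock sigma factor, fell (camera adjusted p from 0.066 to 0.97). The PhoP and PmrA list, with a median of -0.05 and a mean near 0, was tested as higher (adjusted p = 0.91). With a replicate block, the phage shock list was called (adjusted p = 0.0305), as it was without DMSO replicate 1 or without s54-WT replicate 2. In all, limma called 558 genes (13.4%), 308 higher and 250 lower, with a median size of 0.34. Of these 3 higher genes passed a 2-fold change. The number fell to 148 without s54-WT replicate 3, 249 without DMSO replicate 1, 250 without DMSO replicate 2 and 304 without s54-WT replicate 1. It was 1250 against the untreated starved cells, 1199 against both controls, 1521 with library weights and 1147 with a fit on the 2 groups. Under these 4 alternatives the majority was lower, with 637, 617, 810 and 588 genes lower and 613, 582, 711 and 559 higher.

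The largest rises under Ss54-1 were in genes of extracellular polysaccharides. Those for the synthesis and export of colanic acid, the capsular polysaccharide (wcaE 7.06 ± 0.36, wcaG 6.95, wza 6.82 ± 0.23, wzb 5.89, gmd 6.10), for another exopolysaccharide (yjbE 6.57, yjbF 6.16) and for the coactivator of the Rcs phosphorelay, rcsA (5.71 ± 0.31), were among them (log2 units, SE, n = 2 and 3, limma adjusted p = 1.3e-13 for wza). The largest falls were in uhpT, the hexose phosphate transporter gene (-4.66 ± 0.10), the molybdate-binding protein gene modA (-4.26 ± 0.10), flagellar genes (flxA -4.29, flgK -3.56, flgM -3.22), hiuH (-3.29), yhiI (-3.20) and serA, the first enzyme of serine synthesis (-3.08). All 22 members of the Rcs and capsule list rose (median 4.85, camera of limma adjusted p = 5.8e-13, adjusted p = 0.26 with an estimated correlation). Likewise 9 of 11 genes of the Cpx envelope stress response rose, spy by 4.19 (median 0.92, adjusted p = 0.00085, adjusted p = 0.034 with an estimated correlation).

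Nitrogen genes did not move as a block under Ss54-1. Of the 44 NtrC sigma-54 genes 22 rose and 19 fell, with a median of 0.14 and a mean of 0.37 (camera adjusted p = 0.31). The split largely followed operon position, since 11 of 14 first genes fell and 2 rose, while 20 of 30 later genes rose and 8 fell. Genes of the same operon are not independent, so these counts overstate the evidence. In the ast operon astC fell by 1.42 (SE 0.17) and the later astE rose by 1.14. In the ddp operon ddpX was at -0.67 and ddpD at 2.81, and in rut the values were 1.54 for rutA and 2.80 for rutG. Of these, astE, ddpX and rutA were chosen after their values were seen. In glnA and its neighbour glnG they were -0.16 ± 0.05 and 1.15 ± 0.09. Some later genes fell like their first gene, with glnH at -1.14, glnP at -1.02 and glnQ at -1.38. Likewise potF was at -0.88, potG at -1.29 and potH at -0.71. These counterexamples were chosen after their values were seen. The first genes alone had a median of -0.72, and the list was then called lower by camera (adjusted p = 0.024). These genes lay at a median level of 13.33 in DMSO. Near the top of the common distribution rises are limited, and some falls, such as patA at -0.36, are rank steps. The call and the 11 falls may therefore overstate the evidence. Further, glnK fell by 0.96, amtB by 0.70 and relA by 1.61. The values of glnA and amtB were steps from rank 4 to 5 and from rank 1 to 3 of the common distribution, so they do not measure a fold change. Rises were seen for nac (0.37) and rpoN (0.34 ± 0.06, limma adjusted p = 1.1e-04). Transcripts of pspA were not called (0.29, adjusted p = 0.074), except without DMSO replicate 3 or without Ss54-1 replicate 1. Of the other sigma-54 operons 12 of 15 genes fell, the acetoacetate gene atoD by 1.65 (median -0.78, camera adjusted p = 0.0062, adjusted p = 0.37 with an estimated correlation). Of the Nac-activated operons 13 of 16 genes rose, the polyamine transporter gene ydcV by 4.51 and the aminobutyrate permease gene gabP by 4.48 (median 2.32, adjusted p = 7.8e-05, adjusted p = 0.34 with an estimated correlation). Phage shock genes (1 higher, 4 lower), formate genes (3 higher, 12 lower, or 2 and 9 when adjusted over the list alone) and the neighbours of rpoN (4 higher, 1 lower, median 1.24, adjusted p = 0.070) were not called as lists.

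Several biosynthetic and iron genes rose under Ss54-1. All 8 histidine genes rose, hisI by 3.84 (median 2.71, SD of the list's level 0.64 under Ss54-1 and 0.018 in DMSO, camera adjusted p = 6.5e-05, adjusted p = 0.034 with an estimated correlation). So did all 5 tryptophan genes (median 2.04), all 8 methionine genes (median 1.29, metE 2.98) and all 9 ATP synthase genes (median 0.91), each called by camera and each with adjusted p = 0.26 with an estimated correlation. Of 54 ribosomal protein genes 41 rose and 3 fell (median 0.68, adjusted p = 4.4e-06, adjusted p = 0.48 with an estimated correlation). Of 23 iron acquisition genes 22 rose, with fes, enterobactin esterase, at 4.20 (median 1.44, adjusted p = 7.5e-08, adjusted p = 0.26 with an estimated correlation). The sigma-S list (15 higher, 5 lower, median 0.38, katE 3.75), the PhoP and PmrA list (9 higher, 3 lower, median 0.36) and the heat shock list (10 higher, 3 lower, median 0.62, groS 2.93) were called higher by camera at adjusted p = 0.0043, 0.032 and 0.032, against 0.26, 0.26 and 0.47 with an estimated correlation. The heat shock call was lost without Ss54-1 replicate 2. Of 17 SOS genes 14 fell (median -0.77, adjusted p = 0.0052, adjusted p = 0.33 with an estimated correlation). Flagellar genes went both ways (21 higher, 18 lower), with a median of 0.29, a mean of -0.31 and no call by camera, which gave the direction of the mean (adjusted p = 0.85). The glutamate, arginine, branched-chain, pyrimidine, purine, tricarboxylic acid, sigma-E, oxidative stress, efflux and anaerobic lists were not called (adjusted p from 0.066 to 0.57). Limma called 3084 genes (73.9%), 1347 higher and 1737 lower, 505 and 476 of them past a 2-fold change. The median of all genes was -0.10. After centring on the median log ratio it was 0.04, and most called genes were higher (1595, against 1435 lower).

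**Figure D2:**
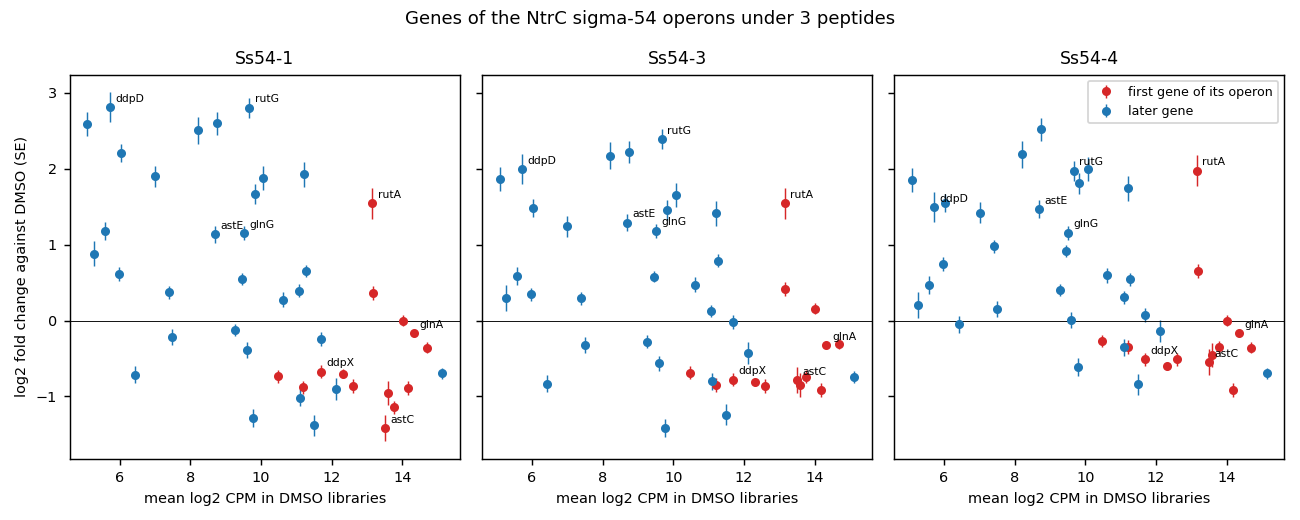
Log2 fold change against DMSO (vertical axis, with SE) and mean log2 CPM in the DMSO libraries (horizontal axis) for the 44 NtrC sigma-54 genes under Ss54-1, Ss54-3 and Ss54-4, with the 14 first genes of operons in red and the 30 later genes in blue. First genes lay at high levels and mostly below 0, with medians of -0.72, -0.76 and -0.36, and later genes mostly above 0, with medians of 0.63, 0.53 and 0.67.

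Under Ss54-2 the nitrogen genes that were higher in starved cells were lower than in DMSO. The arginine catabolism genes astA and astC fell by 7.76 and 7.72 log2 units (SE 0.15 and 0.17, n = 2 and 3, limma adjusted p = 3.5e-18 and 2.8e-17), and rutC and rutB fell by 7.26 and 7.25. Further falls were those of amtB (-6.87 ± 0.08), ddpX (-6.54) and patA (-6.48), and glnK fell by 6.40, to 7.19 ± 0.52 (SD) against 3.50 in nitrogen-rich cells. All 44 NtrC sigma-54 genes fell, with a mean of -4.57 (95% interval -4.69 to -4.45, camera adjusted p = 1.2e-14, adjusted p = 0.070 with an estimated correlation). They included nac (-5.86 ± 0.09), glnG (-1.12 ± 0.09) and glnA (-0.56 ± 0.05). The value of glnA was a change from rank 4 to rank 7 or 8 of the common distribution, so it does not measure a fold change. All 14 first genes and all 30 later genes of the NtrC operons fell. Of the other sigma-54 operons all 15 genes fell, zraP by 5.36 and prpB by 5.28 (median -2.79, adjusted p = 1.7e-05, adjusted p = 0.20 with an estimated correlation). Of 29 formate genes 26 fell, fdhF by 4.05 (median -1.12, adjusted p = 0.0017, adjusted p = 0.23 with an estimated correlation). Transcripts of rpoN fell by 0.25 (SE 0.06, limma adjusted p = 1.1e-03) and of relA by 3.32 (SE 0.10). The phage shock list was not called (1 higher, 4 lower, camera adjusted p = 0.55), and pspA stood at -0.03 (adjusted p = 0.85). Its sign changed with library weights, with centring on the median log ratio and when libraries were left out. Nac-activated operons (7 higher, 5 lower) and the neighbours of rpoN (2 higher, 3 lower, median -0.25, mean 0.17) were not called.

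Growth genes rose under Ss54-2. All 54 ribosomal protein genes did, rplC by 7.46 ± 0.24 and rpsJ by 7.07 (median 3.90, camera adjusted p = 4.4e-17, adjusted p = 0.23 with an estimated correlation). The list's mean level of 11.12 compared with 10.84 in nitrogen-rich and 7.13 in DMSO libraries. The largest rises also included yidD (8.51 ± 0.46), rnpA, the protein of RNase P (6.98), gatB (6.86), the enterobactin genes entC (7.65 ± 0.29) and fes (6.72), and wza (6.73 ± 0.23). All 23 iron acquisition genes rose (median 4.10, adjusted p = 6.6e-10, adjusted p = 0.20 with an estimated correlation). So did all 22 Rcs and capsule genes, wcaE by 6.13 (median 4.14, adjusted p = 5.8e-07, adjusted p = 0.23 with an estimated correlation). All 9 ATP synthase genes (median 2.52), 9 of 13 genes of the tricarboxylic acid cycle (median 2.19), all 11 purine genes (median 2.60), all 8 pyrimidine genes (median 2.75), 10 of 11 arginine genes (median 2.22, carA 5.64), all 8 methionine genes (median 2.07, metE 5.77) and 11 of 13 branched-chain genes (median 1.25) rose. Camera called each at adjusted p between 3.5e-05 and 0.011, but none with an estimated correlation (adjusted p from 0.070 for the branched-chain genes to 0.30 for the tricarboxylic acid cycle). Of 48 flagellar genes 32 rose and 12 fell, flgB by 5.89 upwards (median 1.89, adjusted p = 0.00086, adjusted p = 0.48 with an estimated correlation). Of the Cpx genes 8 of 11 rose (median 0.97, adjusted p = 0.012, adjusted p = 0.12 with an estimated correlation).

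Under Ss54-2, 22 of 25 sigma-S genes fell, wrbA by 4.83 and dps by 3.60 (median -1.61, camera adjusted p = 8.0e-05, adjusted p = 0.12 with an estimated correlation). Of the SOS genes 14 of 17 fell, umuD by 1.90 (median -0.92, adjusted p = 0.0058, adjusted p = 0.25 with an estimated correlation). All 5 tryptophan genes fell, trpE by 4.37 (median -1.78, adjusted p = 0.042, adjusted p = 0.32 with an estimated correlation), a call lost without Ss54-2 replicate 3. The PhoP and PmrA list (5 higher, 8 lower, median -0.20, mean 0.20) and the efflux list (4 higher, 6 lower, median -0.33, mean 0.26) had medians and means of opposite sign and were not called. Neither were the glutamate, histidine, heat shock, sigma-E, oxidative stress and anaerobic lists (camera adjusted p from 0.13 to 0.33). Across 4171 genes the effect of Ss54-2 ran against that of starvation with r = -0.88 and a slope of -0.84, between -0.87 and -0.89 for single libraries, across genes that are not independent replicates. The starved state enters both effects with opposite signs, so a departure from it can push r below 0 and favour opposite calls. Of 3209 genes called in both comparisons, 3019 (94.1%) went in opposite directions. Of the starvation rise in the NtrC list, Ss54-2 reversed a median of 82.4% (42 genes raised at least 2-fold). Here reversed means lower than in DMSO at the time sampled, whether or not the rise had first taken place. The share was 111% for the other sigma-54 operons (15 genes), 90.9% for raised genes outside the sigma-54 lists (958 genes), 63.4% for the sigma-S list (20 genes) and 24.1% for the phage shock list (5 genes). Limma called 3559 genes (85.3%), 1596 higher and 1963 lower, with 1050 and 1150 past a 2-fold change. After centring on the median log ratio the excess of lower genes nearly vanished, at 1774 higher and 1798 lower.

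**Figure D3:**
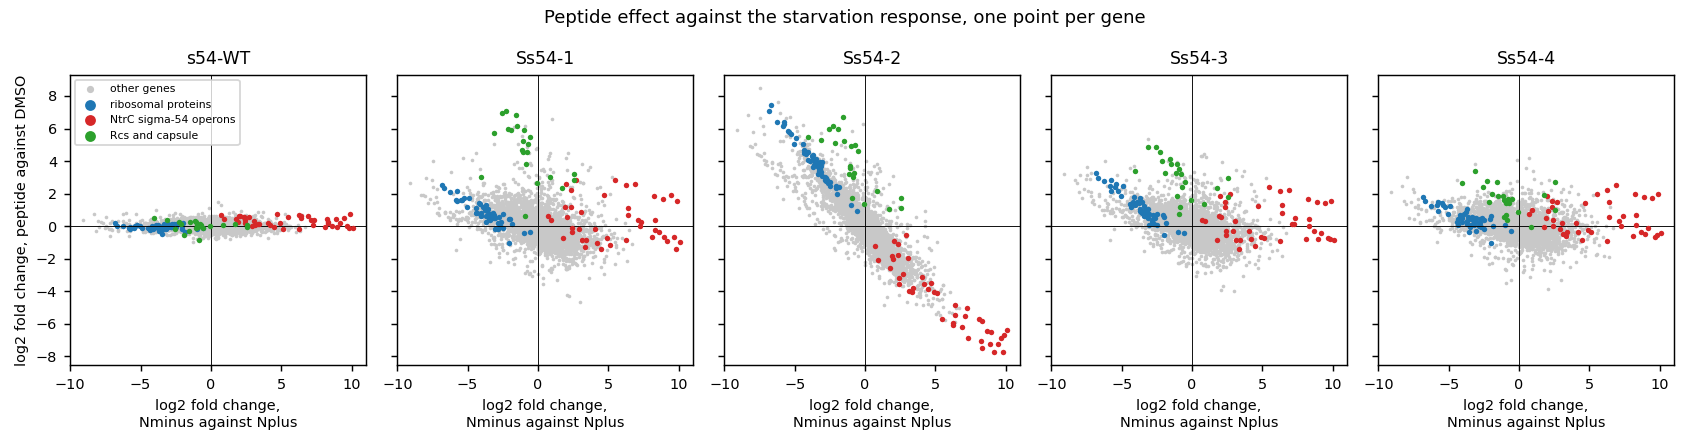
Log2 fold change of each peptide against DMSO (vertical axis) plotted on the log2 fold change of untreated starved against nitrogen-rich cells (horizontal axis), with a point per gene, a panel per peptide and 3 gene lists in colour. Ss54-2 ran against starvation with r = -0.88, Ss54-1, Ss54-3 and Ss54-4 with r = -0.40, -0.45 and -0.31, and s54-WT with r = -0.05, while Rcs and capsule genes (green) stood above the trend under Ss54-1 to Ss54-4. Both axes hold the starved state with opposite signs, which can push r below 0 without a move towards nitrogen-rich cells. Group means of Ss54-1, Ss54-3 and Ss54-4 correlated with nitrogen-rich means at r = 0.757, 0.772 and 0.741. DMSO stood at 0.718 and Ss54-2 at 0.938.

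Ss54-3 gave the largest rise to iraM, an anti-adaptor that stabilises sigma-S (5.38 ± 0.32 log2 units, SE, n = 2 and 3, limma adjusted p = 1.7e-10). Next came the Rcs coactivator gene rcsA (4.88 ± 0.31), the capsule genes wcaG (4.84) and wcaE (4.54), and the acid shock gene asr (4.43 ± 0.24). They were followed by asnB (4.34 ± 0.26), ydgU (4.30) and yjbE (4.22), of another exopolysaccharide. The largest falls were in uhpT (-4.01 ± 0.10), modA (-3.94 ± 0.10), flxA (-3.70), flgK (-2.81), yhiI (-3.09), stpA (-3.06), hscB, a chaperone of iron-sulphur cluster assembly (-2.89), and hiuH (-2.84). All 22 Rcs and capsule genes rose (median 3.25, camera adjusted p = 6.3e-10, adjusted p = 0.28 with an estimated correlation). The same held for 9 of 11 Cpx genes, spy by 2.93 (median 0.66, adjusted p = 0.0031, adjusted p = 0.13 with an estimated correlation). It also held for 11 of 16 PhoP and PmrA genes, pagP by 2.46 (median 0.55, adjusted p = 0.0019, adjusted p = 0.13 with an estimated correlation).

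Of the 44 NtrC sigma-54 genes 20 rose and 20 fell under Ss54-3 (21 and 20 when adjusted over the list alone), with a median of 0.14 and no call by camera (adjusted p = 0.41). Again 11 of 14 first genes fell and 18 of 30 later genes rose, with rutG at 2.39 and rutE at 2.22. The first genes alone had a median of -0.76 (camera adjusted p = 0.027). This call has the same limit near the top of the common distribution as under Ss54-1. Single nitrogen genes were glnG (1.18 ± 0.09), rpoN (0.41) and nac (0.41), which rose, and glnA (-0.32), glnK (-0.86), amtB (-0.74), astC (-0.78) and relA (-1.68), which fell (limma adjusted p of 4.7e-04 for astC). Here glnA went from rank 4 to 6 and amtB from rank 1 to 3 or 4, so these 2 values are rank steps. Transcripts of pspA rose by 0.71 ± 0.14 (limma adjusted p = 1.9e-04) and pspG by 1.27, but the phage shock list was not called (2 higher, 4 not called, median -0.03, mean 0.28, camera adjusted p = 0.41). Of the other sigma-54 operons 13 of 15 genes fell and 1 rose, atoD by 1.40 downwards (median -0.81, camera adjusted p = 0.0038, adjusted p = 0.32 with an estimated correlation). Of 29 formate genes 14 fell (median -0.44, adjusted p = 0.043, adjusted p = 0.36 with an estimated correlation), a call lost without DMSO replicate 1 or without Ss54-3 replicate 2. Of the Nac-activated operons 13 of 16 genes rose, gabP by 3.94 (median 2.00, adjusted p = 0.00018, adjusted p = 0.32 with an estimated correlation).

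Ribosomal protein genes rose under Ss54-3 in 45 of 54 cases (46 when adjusted over the list alone), with a median of 0.98 (camera adjusted p = 1.4e-09, adjusted p = 0.36 with an estimated correlation) and mean levels of 7.91 and 8.63 in its libraries. Iron acquisition (22 of 23 higher, median 1.14, entC 4.02), ATP synthase (9 of 9, median 1.07), tryptophan (5 of 5, median 2.66, trpA 2.86), methionine (7 of 8, median 1.39, metE 3.16), histidine (8 of 8, median 0.72) and purine genes (10 of 11, median 0.47) were called higher by camera at adjusted p between 5.1e-07 and 0.0084, with adjusted p of 0.22 to 0.32 with an estimated correlation. The sigma-S list (14 higher, 4 lower, katE 2.97) was called higher at adjusted p = 0.018 (0.31 with an estimated correlation) and not without Ss54-3 replicate 1. Of 17 SOS genes 14 fell (median -0.66, adjusted p = 0.0081, adjusted p = 0.32 with an estimated correlation). Branched-chain genes (6 higher, 7 lower, median -0.40, mean 0.11) and flagellar genes (25 higher, 17 lower, or 26 and 17 when adjusted over the list alone) were not called. Neither were the neighbours of rpoN (4 higher, 1 lower) and the glutamate, arginine, pyrimidine, tricarboxylic acid, heat shock, sigma-E, oxidative stress, efflux and anaerobic lists (camera adjusted p from 0.064 to 0.87). Limma called 3048 genes (73.1%), 1354 higher and 1694 lower, with 497 and 407 past a 2-fold change. After centring on the median log ratio the balance turned, to 1594 higher and 1400 lower.

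Ss54-4 raised both asparagine synthetase genes, asnB by 4.19 ± 0.26 and asnA by 3.57 ± 0.21 log2 units, and the cold shock genes cspA by 4.07 ± 0.19 and cspI by 2.90 (SE, n = 2 and 3, limma adjusted p = 5.0e-10 for asnB and 2.1e-11 for cspA). They were followed by iraM (3.81 ± 0.32), yjbE (3.38), rcsA (3.38 ± 0.31) and metE (3.03). The largest falls were in modA (-3.90 ± 0.10), yhjH, a cyclic di-GMP phosphodiesterase gene (-3.49), uhpT (-3.32), ves (-3.31), yeeD (-3.14), stpA (-2.83), flxA (-2.80) and flgM (-2.71). Of 22 Rcs and capsule genes 20 rose, wcaE by 2.74 (median 1.66, camera adjusted p = 3.7e-06, adjusted p = 0.56 with an estimated correlation). The list's median was 1.03 without Ss54-4 replicate 3. Iron acquisition genes were not called as a list (7 higher, 4 lower, or 5 and 0 when adjusted over the list alone, median 0.06, camera adjusted p = 0.46), although fes rose by 1.58 and entC by 1.50.

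Of the 44 NtrC sigma-54 genes 22 rose and 15 fell under Ss54-4, with a median of 0.26 and a mean of 0.49 (camera adjusted p = 0.048, adjusted p = 0.56 with an estimated correlation). For the NtrC sigma-54 operons list, Ss54-4 against DMSO, the camera call was lost without Ss54-4 replicate 2 (adjusted p = 0.165), at a mean CPM of at least 10 (adjusted p = 0.0999) and after centring on the median log ratio (adjusted p = 0.0538). Of the first genes 11 of 14 fell, and their median of -0.36 was not called (adjusted p = 0.088). These falls have the same limit near the top of the common distribution as under Ss54-1. Of later genes 20 of 30 rose and 4 fell, with rutE at 2.52. Among single genes glnG (1.16), nac (0.65) and rpoN (0.41) rose, and amtB (-0.70), relA (-1.23) and glnA (-0.16) fell (limma adjusted p of 4.7e-03 for glnA). The values of amtB and glnA were the steps from rank 1 to 3 and from rank 4 to 5, as under Ss54-1, so they do not measure a fold change. The fall of glnK (-0.45, limma adjusted p = 0.019) was not called without either Ss54-4 library, nor that of astC (-0.55, level 12.95 ± 0.53 SD) without Ss54-4 replicate 3. Transcripts of pspA were not called (0.08, adjusted p = 0.64). Nac-activated operons rose in 13 of 16 genes, gabP by 2.84 (median 1.48, camera adjusted p = 0.0012, adjusted p = 0.56 with an estimated correlation). Other sigma-54 operons fell in 9 of 15 genes, norW by 1.08 (median -0.69, adjusted p = 0.048, adjusted p = 0.56 with an estimated correlation), a call lost without DMSO replicate 3, without Ss54-4 replicate 3 or with a replicate block. Formate genes (10 lower, 9 when adjusted over the list alone) and phage shock genes (3 lower) were not called as lists.

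Tryptophan (5 of 5, trpE 2.64), methionine (7 of 8, metF 1.70), ribosomal (29 higher, 3 lower of 54, median 0.41), Cpx (8 of 11, yebE 2.01), PhoP and PmrA (9 of 16, pagP 1.61) and ATP synthase genes (6 of 9) were called higher under Ss54-4 by camera at adjusted p between 0.00047 and 0.048, and with adjusted p of 0.45 to 0.65 with an estimated correlation. The ATP synthase call was lost without Ss54-4 replicate 3, and the PhoP and PmrA call without Ss54-4 replicate 3, without DMSO replicate 2 or with a replicate block. SOS genes (2 higher, 12 lower, camera adjusted p = 0.066) and flagellar genes (15 higher, 17 lower, median 0.08, mean -0.20) were not called, nor were the remaining lists (camera adjusted p from 0.066 to 0.87). Among these the arginine list (median 0.06, mean -0.07) and the pyrimidine list (median -0.16, mean 0.23) differed in sign between median and mean. Limma called 2760 genes (66.2%), 1303 higher and 1457 lower, with 351 and 265 past a 2-fold change. Centring on the median log ratio turned the balance to 1470 higher and 1245 lower.

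**Figure D4:**
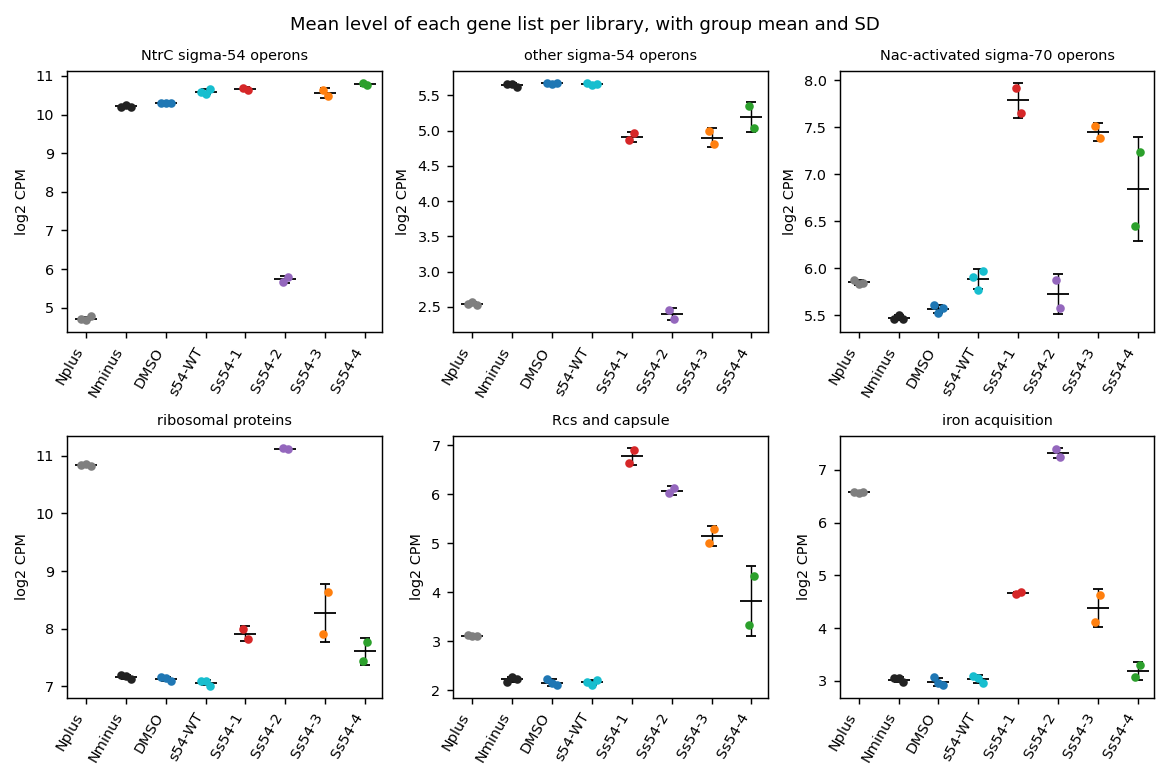
Mean log2 CPM of 6 gene lists in each library, by group, with the group mean (bar) and SD (whiskers). The Ss54-2 libraries had NtrC sigma-54, ribosomal and iron levels near those of nitrogen-rich cells (5.73, 11.12 and 7.32 against 4.72, 10.84 and 6.57), and all of Ss54-1 to Ss54-4 had capsule levels above the 2.16 of DMSO, from 3.83 for Ss54-4 to 6.77 for Ss54-1.

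The peptides were compared pair by pair at the same nominal dose and time. The NtrC list separated Ss54-2 from the other 4. Its mean was 4.86 log2 units lower under Ss54-2 than under s54-WT (difference -4.86, 95% interval -4.98 to -4.74), with differences of -4.94 (-5.07 to -4.80) from Ss54-1, 4.83 (4.69 to 4.96) for Ss54-3 minus Ss54-2 and 5.05 (4.92 to 5.19) for Ss54-4 minus Ss54-2. All were called by camera, and with an estimated correlation the adjusted p was 0.056 against s54-WT, 0.012 for Ss54-1, 0.012 for Ss54-3 and 0.027 for Ss54-4. Among the others the NtrC means lay close together. The difference was 0.08 (-0.04 to 0.20) for Ss54-1 minus s54-WT, -0.03 (-0.15 to 0.09) for Ss54-3 minus s54-WT and 0.19 (0.07 to 0.31) for Ss54-4 minus s54-WT. It was -0.11 (-0.24 to 0.02) for Ss54-3 minus Ss54-1, 0.12 (-0.01 to 0.25) for Ss54-4 minus Ss54-1 and 0.23 (0.10 to 0.36) for Ss54-4 minus Ss54-3. The medians of Ss54-1 minus s54-WT (-0.09) and Ss54-4 minus s54-WT (-0.05) were opposite in sign to the means. Camera called only the last of these 6 (adjusted p = 0.0025, adjusted p = 0.38 with an estimated correlation), and it called Ss54-3 minus Ss54-1 with a replicate block or without Ss54-3 replicate 1. Without Ss54-3 replicate 1 the means of Ss54-3 minus s54-WT and Ss54-1 differed by -0.12 and -0.19, and without Ss54-3 replicate 2 by 0.05 and -0.02. Ss54-4 minus Ss54-3 was 0.14 without Ss54-3 replicate 2, and Ss54-1 minus s54-WT was 0.05 without s54-WT replicate 2. The other sigma-54 operons had lower means under Ss54-1 than under s54-WT (-0.75, -0.91 to -0.60), with a difference of -0.01 (-0.18 to 0.16, median 0.03) between Ss54-3 and Ss54-1, of either sign when single libraries were left out (-0.10 to 0.08).

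Capsule genes graded the peptides. The list's mean was higher than under s54-WT by 4.61 (4.21 to 5.01) for Ss54-1, 3.91 for Ss54-2, 2.98 for Ss54-3 and 1.67 (1.27 to 2.06) for Ss54-4. It was lower under Ss54-3 than under Ss54-1 (-1.63, -2.07 to -1.19, camera adjusted p = 2.9e-18, adjusted p = 0.091 with an estimated correlation). It was also lower under Ss54-4 than under Ss54-3 (-1.31, -1.75 to -0.88, adjusted p = 5.1e-10, adjusted p = 0.20 with an estimated correlation), or by 0.81 without Ss54-4 replicate 2. The list's level varied more under Ss54-4 (SD 0.71) than under Ss54-3 (0.20) or s54-WT (0.055), so the shared spread may make the Ss54-4 intervals too narrow. The difference of Ss54-2 from Ss54-1 was -0.70 (-1.13 to -0.26) and was not called by camera (adjusted p = 0.088). Iron genes were 2.65 (2.40 to 2.90) higher under Ss54-2 than under Ss54-1 and lower under Ss54-4 than under Ss54-1 (-1.48, -1.73 to -1.22, adjusted p = 1.7e-14, adjusted p = 0.13 with an estimated correlation). The difference of Ss54-4 from s54-WT was 0.16 (-0.08 to 0.39), or 0.04 without Ss54-4 replicate 3. Histidine genes were lower under Ss54-3 than under Ss54-1 (-1.63, adjusted p = 0.00045 with an estimated correlation) and Ss54-4 than Ss54-1 (-2.35, adjusted p = 0.0041 with an estimated correlation). The histidine list's level had an SD of 0.64 under Ss54-1, 0.22 under Ss54-3 and 0.34 under Ss54-4, so the size of these differences is uncertain. Phage shock genes were higher under Ss54-3 than under Ss54-1 (0.56, 0.34 to 0.78, adjusted p = 0.00015, adjusted p = 0.14 with an estimated correlation). Nac-activated genes were lower under Ss54-4 than under Ss54-1 (-0.94, -1.31 to -0.58, camera adjusted p = 0.00019, adjusted p = 0.40 with an estimated correlation), and the difference was -0.55 without Ss54-4 replicate 2. Their level had an SD of 0.55 under Ss54-4 and 0.19 under Ss54-1, so this interval may be too narrow as well.

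Ss54-1 and Ss54-3 differed in the fewest genes, 620 by limma, 315 higher and 305 lower under Ss54-3, with 14 and 48 past a 2-fold change, or 296 higher and 318 lower after centring on the median log ratio. The largest were ssuD (-2.88), hisF (-2.82) and wcaA (-2.73) downwards and ves (1.26), tsr (1.22) and trpL (1.19) upwards. Ss54-4 differed from Ss54-1 in 1935 genes and from Ss54-3 in 1677. The Rac prophage gene ynaE and its relative ydfK were higher under Ss54-4 (2.69 and 2.85 against Ss54-1, 2.05 and 1.89 against Ss54-3), as were asnA against Ss54-1 (2.43) and cspA against Ss54-3 (1.77). Capsule genes were lower (gmd -4.60 and wcaG -4.56 against Ss54-1, wcaH -2.51 against Ss54-3), as were the enterobactin genes entC (-2.52) and ybdZ (-2.73 ± 0.96, limma adjusted p = 0.032) against Ss54-3. Ss54-2 differed from Ss54-1, Ss54-3 and Ss54-4 in 3211, 3220 and 3337 genes. It had lower rutB than Ss54-1 (-9.17) and lower csiD (-7.58), a starvation-induced gene of glutarate use, and higher yidD (6.08) and malK, of the maltose transporter (5.76). Against it Ss54-3 and Ss54-4 had higher rutD (8.73 and 9.07), and lower yidD (-4.88 and -6.44). Against s54-WT, limma called 2988, 3568, 2908 and 2465 genes for Ss54-1 to Ss54-4. Here wza was 7.15 higher under Ss54-1, astA at -7.96 under Ss54-2, iraM 5.15 higher under Ss54-3 and modA at -3.30 under Ss54-4. Of the called genes, 43.3% were higher under Ss54-3 than under s54-WT, and 53.5% after centring on the median log ratio. With library quality weights the genes that separated Ss54-3 from Ss54-1, Ss54-4 from Ss54-1 and Ss54-4 from Ss54-3 numbered 320, 1025 and 662, and with fits on the 2 groups 103, 690 and 98. For Ss54-3 against Ss54-1 most were then lower, 175 of 320 and 74 of 103, as were 348 of 662 and 61 of 98 for Ss54-4 against Ss54-3. Between Ss54-3 and Ss54-1 278 genes were called without Ss54-1 replicate 1 and 369 without Ss54-3 replicate 2. Between Ss54-4 and Ss54-3 1037 were called without Ss54-3 replicate 2 and 1076 without Ss54-4 replicate 2.

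The peptides shared many called genes. Ss54-1 and Ss54-3 changed 2718 genes in the same direction and 10 in opposite directions, where independent calls would give 437 shared rises and 705 shared falls. Ss54-1 and Ss54-2 shared 2330, with 433 opposite, Ss54-1 and Ss54-4 shared 2225, with 119 opposite, and Ss54-3 and Ss54-4 shared 2293. Of the 558 genes of s54-WT, 507 were shared with Ss54-4 in the same direction and 11 were opposite, against 341 and 164 with Ss54-2. All these contrasts use the same DMSO libraries. In 50 simulations with unchanged groups, the shared libraries alone gave the log2 fold changes a covariance of 0.00819 for Ss54-1 and Ss54-3 and 0.00825 for s54-WT and Ss54-4, against measured covariances of 0.910 and 0.0968. With the second peptide set against the untreated starved libraries, Ss54-1 and Ss54-3 shared 2701 genes and s54-WT and Ss54-4 shared 515. Among genes named for single peptides, modA was at -0.60, -4.26, -3.43, -3.94 and -3.90 under s54-WT, Ss54-1, Ss54-2, Ss54-3 and Ss54-4, and uhpT at -0.29, -4.66, -4.66, -4.01 and -3.32 (all called by limma). In the same order asnA was at 1.50, 1.15, 1.99, 2.07 and 3.57, all called, while asnB was at 1.27, 4.15, 0.22, 4.34 and 4.19, called under all but Ss54-2 (adjusted p = 0.43).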

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

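Of the tests in this part, the share of the starvation rise reversed outside sigma-54 genes and the Rcs-regulated genes outside the capsule operon were chosen only after the result was seen. Differences between peptides stood out where a list went up under 1 peptide and down under another and camera of limma called the difference itself. No test of single outlying libraries was run, and groups of 2 and 3 libraries on their own are too small for it.

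Each difference is given as the median over the list's genes of the difference between the peptides in log2 units, which is not the difference of the medians against DMSO. For the NtrC sigma-54 list it was -4.68 for Ss54-2 minus s54-WT (camera adjusted p = 1.1e-15, adjusted p = 0.056 with an estimated correlation) and 4.96 for Ss54-4 minus Ss54-2 (adjusted p = 4.9e-19, adjusted p = 0.027 with an estimated correlation). Against DMSO the medians of this list were -4.49 for Ss54-2, 0.31 for s54-WT and 0.26 for Ss54-4. For the tryptophan list it was -2.24 for Ss54-2 minus s54-WT (camera adjusted p = 0.021), -3.81 for Ss54-2 minus Ss54-1 (adjusted p = 0.0011), 4.31 for Ss54-3 minus Ss54-2 (adjusted p = 0.00074) and 3.52 for Ss54-4 minus Ss54-2 (adjusted p = 0.0031). With an estimated correlation none of these 4 was called (adjusted p = 0.27, 0.18, 0.17 and 0.17). For the sigma-S list it was -2.32 for Ss54-2 minus Ss54-1 (adjusted p = 2.0e-10) and 2.24 for Ss54-3 minus Ss54-2 (adjusted p = 1.3e-09), both with adjusted p = 0.012 with an estimated correlation.

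The Ss54-2 libraries lay close to the nitrogen-rich ones. Libraries made only of other groups' RNA, mixed or under a wrong label, would hold almost no gene far above every library of those groups. Yet 25 genes were more than 1 log2 unit above all of them in both Ss54-2 libraries, cspA at 13.58 against at most 11.80 and sbp at 8.42 against 6.46. A loss of starvation induction limited to sigma-54 promoters, with no effect further on, would leave other raised genes up. Instead a median share of 0.909 of their rise was reversed over 958 genes, so the reversal was not confined to the sigma-54 lists. Genes further on could fall as a consequence, since the regulator nac, on the NtrC list, was itself at -5.86 against DMSO. The share cannot separate such a consequence from a wider loss. The first test argues against libraries made wholly of other groups' RNA. Other groups' RNA mixed into true Ss54-2 RNA could keep such genes high, and an exchange of labels between whole groups would leave the same genes apart. Neither was tested. A candidate explanation that stays open, untested, is that Ss54-2 kept or returned cells to a state of nitrogen sufficiency or growth, and whether growth continued is not given in the sources used here.

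Capsule genes were higher under Ss54-1 to Ss54-4. If their low level in DMSO and the normalization were the cause, genes of matched level would rise alike, but the largest of the 4 ratios of the matched genes' median to that of the capsule list was 0.0114. If Rcs signalling were raised more widely, Rcs-regulated genes outside the list and the capsule operon would rise by over 1 log2 unit, but the smallest of the 4 medians over 8 such genes was 0.599 (Ss54-4, 5 higher and 1 lower), against 2.42, 2.97 and 1.00 under Ss54-1, Ss54-2 and Ss54-3. Of these genes 4 are the single yjb operon, whose yjbE and yjbF had been seen among the largest rises, and ypdI fell under all 4 peptides. The values therefore leave open whether a wider Rcs response, which senses envelope stress, accompanied the capsule genes.

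Under Ss54-1, Ss54-3 and Ss54-4 later genes of NtrC operons stood above first genes by 1.35, 1.29 and 1.03 log2 units. The difference was 2.06 under Ss54-2, where both kinds of genes fell, and 0.44 under s54-WT. First genes lie near the ceiling of the common distribution, which might press them down. Under Ss54-1, Ss54-3 and Ss54-4, however, the largest share of the difference shown by genes of matched level was 0.0147. The matched genes of first genes lay a median of 0.79 and up to 2.11 log2 units away in level, so the ceiling is poorly matched at the very top. A gradient along operons in general cannot be told apart from an effect on these operons, since over 31 other operons the largest of the 3 medians was 0.0588 (Ss54-4, 95% interval -0.29 to 0.41) and the interval of Ss54-1 ran from -0.30 to 0.31. Slower RNA decay at the 3' end, or transcripts started before treatment, could not be tested with one value per gene.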

How the results depend on the processing

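Centring on the median log ratio was the test chosen only after the data were seen. Over the values that answer a comparison, 410 recomputed values kept their direction, side of the threshold or size, 23 moved, 3 reversed, 10 became weaker and 1 stronger. Over the other values, which are single genes, other lists and the NtrC list between peptides, 12515 kept theirs, 325 became weaker, 27 stronger and 23 reversed. Outside the pairs of peptides, an estimated correlation ended 70 list calls apart from the NtrC list. Depth is unknown, so what it limits cannot be stated. Library-median centring and a repeated quantile normalization change almost nothing in values already normalized in this way, and so test little. Centring on the median log ratio moved the median of all genes against DMSO by over 0.1 for Ss54-1 (from -0.10 to 0.04), Ss54-2 and Ss54-3, and by less for Ss54-4, s54-WT and starvation. With it the majority of called genes turned from lower to higher for Ss54-1, Ss54-3 and Ss54-4, against DMSO and against s54-WT, and from higher to lower for Ss54-3 against Ss54-1 and Ss54-2 and for Ss54-4 against Ss54-1 and Ss54-3. Unless a construction is named, the cause was not tested.

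Library quality weights gave 110 genes for DMSO against Nminus, 1521 for s54-WT against DMSO, 320 for Ss54-3 against Ss54-1, 1025 for Ss54-4 against Ss54-1 and 662 for Ss54-4 against Ss54-3, and 0.0231 for pspA under Ss54-2. The share of higher genes for DMSO against Nminus went from 90.0% to 46.4%. Fits on the 2 groups, which estimate the spread from fewer libraries, gave 17, 1147, 103, 690 and 98 genes in the same order. For s54-WT, the untreated starved cells as control gave 1250 genes, hiuH at 1.83, since DMSO itself raised hiuH, and the other sigma-54 list at 0.0251, and the mean control gave 1199, 0.506 and 0.0214. That list gave 0.00507 at a mean CPM of at least 10, and none of its values was called. The NtrC list under Ss54-4 gave 0.255 at a mean CPM of at least 10 (adjusted p = 0.0999), 0.336 with the median log ratio (adjusted p = 0.0538), 0.255 with an estimated correlation (adjusted p = 0.56) and -0.356 for first genes of operons (adjusted p = 0.088). First genes gave 0.00618 for DMSO against Nminus, 0.00 for s54-WT, -0.718 for Ss54-1 and -0.760 for Ss54-3. An estimated correlation ended the NtrC call at 0.0772 for DMSO against Nminus, 0.307 for s54-WT and -4.49 for Ss54-2, which changes the variance and not the median. By fry, which tests the genes on their own and not against others, the NtrC list at 0.0772 was not called for DMSO against Nminus and at 0.137 was called for Ss54-1. The median log ratio gave 0.124 for pspA under Ss54-2, 0.0999 for the phage shock list under Ss54-3, and 0.0516 and 0.0258 for the NtrC list of Ss54-1 and Ss54-4 against s54-WT. Without the NtrC list the correlation of the effect with starvation was -0.0897 for s54-WT and -0.438 for Ss54-1.

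With each library left out in turn, the genes of s54-WT against DMSO numbered from 148 (without s54-WT replicate 3) to 445, with 249 without DMSO replicate 1, 250 without DMSO replicate 2 and 304 without s54-WT replicate 1. For Ss54-3 against Ss54-1 they ran from 278 (without Ss54-1 replicate 1) to 599, with 369 without Ss54-3 replicate 2. For Ss54-4 against Ss54-3 they ran from 1037 (without Ss54-3 replicate 2) to 1911, with 1076 without Ss54-4 replicate 2. The NtrC list under Ss54-4 ran from 0.226 to 0.310, the latter without Ss54-4 replicate 2 and not called (adjusted p = 0.165). The following were not called in any case. The ranges were -0.295 to 0.236 for pspA under Ss54-2, -0.111 to 0.0548 for pspA and -0.0272 to 0.0685 for glnG under DMSO against Nminus, -0.113 to 0.0863 for the phage shock list under Ss54-3, -0.0712 to 0.0212 for the formate list under s54-WT and -0.0779 to 0.0122 for the NtrC list of Ss54-4 against s54-WT. The correlation of s54-WT with starvation ran from -0.0629 to -0.0156.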

Other observations

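Tests of gene families by shared prefix, and the families and genes in this part, were chosen only after the data were seen. In starved cells all 7 puu genes, for putrescine use, rose (median 3.85, puuA 4.24), as did all 7 universal stress protein genes of the usp family (median 2.74, uspB 6.36), and under Ss54-2 all members of the puu and usp families fell (medians -3.14 and -2.94). All 14 thi genes, for thiamine synthesis, fell in starvation (median -1.44). The waa genes, for the lipopolysaccharide core, fell in 14 of 15 cases in starvation (median -1.19) and rose in 14 of 15 under Ss54-1 (median 0.71), 15 of 15 under Ss54-2 (1.26), 15 of 15 under Ss54-3 (0.93) and 14 of 15 under Ss54-4 (0.75). Subunits of respiratory complex I, the nuo family, rose in 11 of 13 cases under s54-WT (median 0.35) and 12 of 13 under Ss54-4 (median 0.84, nuoN 1.03), and the oligopeptide transporter genes of the opp family in 3 of 5 and 5 of 5 (medians 0.38 and 1.39, oppB 0.81 and 2.00). Under Ss54-4, 11 of 18 cys genes, for sulphate uptake and cysteine synthesis, fell and 2 rose (median -0.83, cysP -2.69). Camera of limma called each of these, with adjusted p of 1.7e-07 for nuo under s54-WT and 0.00011 for waa under Ss54-3, and none with an estimated correlation (adjusted p = 0.94 and 0.84 for these).

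Of the 9 genes that DMSO raised, 9, 7, 7 and 6 were lower under Ss54-1 to Ss54-4 than in DMSO, and 0, 1, 0 and 2 were higher. Under s54-WT 2 were lower, 1 was higher and 6 were not called, and the 9 genes were not tested as a set. Against DMSO, torC was at -1.99, -2.16, -2.28 and -1.34 under Ss54-1 to Ss54-4, yedY at -2.03, -4.22, -1.79 and -1.22 and hiuH at -3.29, -4.84, -2.84 and -1.73, all called by limma, while torC under s54-WT (-0.30, adjusted p = 0.10) and torA under Ss54-4 (-0.24, adjusted p = 0.23) were not, and torD was higher under Ss54-4 (0.67). Of the 5 isc genes, for iron-sulphur cluster assembly, 4 were lower and 1 was higher under each of Ss54-1 to Ss54-4, but the isc family was not called by camera (adjusted p = 0.23, 0.28, 0.19 and 0.12). Among them iscU was at -2.62, -2.10, -2.68 and -1.94, and was not called under s54-WT (-0.13, adjusted p = 0.61). The molybdate uptake genes after modA fell as well, modB by 2.38, 2.00, 2.22 and 2.07 and modC by 1.94, 1.55, 2.00 and 1.96 under the same 4 peptides, although the mod family was not called by camera (adjusted p from 0.19 to 0.35). The acid shock gene asr was at 3.50, 3.82, 4.43 and 2.20 and iraM at 5.02, 5.74, 5.38 and 3.81 under them, all called, and neither was called under s54-WT. The csp genes picked here did not all move together, and other members, such as cspI, are not counted. Transcripts of cspA were at 6.30 ± 0.19 under Ss54-2 and 1.66 under Ss54-1. Under Ss54-1 cspG (-1.21), cspE (-0.67) and cspD (-1.27) fell, while under Ss54-2 cspE (1.14) and cspG (0.93) rose with cspA and cspD fell (-2.92).

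Each of the 3 comparisons with 3 libraries on both sides can be regrouped in 10 splits. The real split, counted as 1 split with a result as large, gave 3592 genes for Nminus against Nplus, 10 for DMSO against Nminus and 558 for s54-WT against DMSO, and the highest of the other 9 splits gave 0 in each. With 10 splits no share under 0.05 is possible. Every other split mixes both groups, so a real difference between them turns into spread within the split groups. The counts of 0 therefore tell little.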
